A study of Mus musculus with 6 samples.

How the data were processed

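Expression was measured in RAW 264.7 cells, 3 samples with a non-targeting control GapmeR and 3 with a GapmeR against Mist, transfected at 50 nM and collected at 48 h. Per the labels, total RNA was purified on columns with DNase digestion, and 5 µg per sample was labelled with biotin by a protocol of the array maker Affymetrix. The deposited values are log2 expression, 1 column per array; RMA, a summary of probe intensities with background correction and quantile normalization, and Partek are named in the submitters' processing notes without versions or roles. The array design and the settings of these steps are not given in the sources used here. RMA draws the arrays to a shared distribution, so a change of most transcripts in the same direction would be reduced in these values. The log2 values were used as deposited, and they ranged from 2.50 to 14.1.

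Samples were grouped by the GapmeR named in the labels. The labels give no batch, and nothing in them says that the replicates are separate cultures, so p values measure the spread between these samples, which may be technical. No 2 columns were identical, correlations between arrays were 0.988 to 0.991 within groups and 0.986 to 0.989 between groups, and 0 columns of per-sample values were left unused.

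Probe sets were named from a table of the platform annotation. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 were not listed, which leaves them unnamed here. Gene IDs of 23328 of the single-gene probe sets were matched in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. The same table, sorted by start position on the chromosome of Fabp5, gave the genes that neighbour it. The list of genes around the Fabp cluster was fixed beforehand and not taken from that order. Mist is not a symbol in the annotation, and the genes with similar aliases, Clnk and Bhlha15, were not taken for it. No probe set could be recognised as a control probe set, so all 41345 were tested, although the plan was to leave control probe sets out. A gene was read at 1 probe set, that with the highest mean over all 6 arrays among probe sets listed with that gene alone; 1082 genes had more than 1.

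Differences are Mist-targeted minus Control on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with SE from the moderated variance (prior degrees of freedom 3.48). Adjusted p values follow Benjamini and Hochberg over all 41345 probe sets, and a call is an adjusted p under 0.05. An exact permutation test of 3 against 3 cannot go below p = 0.1, so single genes were read from this model. Gene lists were tested on 1 value per gene with camera at a preset correlation of 0.01, adjusted over 33 lists, each with at least 5 measured members. Camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in 1 direction or change in either, were alternatives; fry does not compare a list with other genes. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

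The lists were fixed before the data were examined, as were the tests, the alternatives other than that named as added and the rule for named genes. They cover interferon-stimulated genes, inflammatory cytokines and chemokines, the NF-kB pathway, toll-like receptor and nucleic acid sensing, alternative activation, macrophage identity, antigen presentation, fatty acid binding and lipid storage, genes around the Fabp cluster, cholesterol biosynthesis, LXR targets and lipogenesis, fatty acid oxidation, oxidative phosphorylation, glycolysis, hypoxia targets, NRF2 targets, p53 targets, endoplasmic reticulum chaperones, the integrated stress response, heat shock, S phase, G2 and mitosis, ribosome biogenesis and MYC targets, lysosome and autophagy, the PARP family, osteoclast genes and apoptosis regulators. Further lists hold markers of T and NK cells, B cells, neutrophils, dendritic cells, fibroblasts, and erythroid and mast cells. Some genes stand on more than 1 list.

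Named genes are the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap. They further include, per list, up to 4 members past the threshold by size or, where none passes, up to 2 with the smallest p. Always named are Fabp5, Fabp4, Tnf, Il1b, Il6, Ccl2, Nos2, Cxcl10, Arg1, Mrc1, Parp1 and Csf1r. Symbols of the form Gm, Rik or LOC with numbers were counted and not named, which left 88 of 92 called genes open to naming. Of the 105 probe sets called (53 rose and 52 fell), 7 had no listed gene, 4 had several genes and 2 were further probe sets of a gene.

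Alternatives were the replicate number as a block, eBayes with trend and robust, a model without moderation, leaving out the dimmest 40% of probe sets, quantile normalization, median centring, array weights, a minimum change of 1.5-fold, the mean of all probe sets of a gene, and leaving out each array in turn. Testing only listed probe sets was added after seeing the data. The fit was tested on simulated data of 41345 probe sets with 200 changed and with noise drawn independently for each probe set. Such data cannot show how the list test behaves where genes are correlated. It called 74% of those changed by 1 log2 unit and 96% of those changed by 2, and of its 184 calls 170 were changed probe sets, 1 belonged to a shifted list and 13 were not changed; both shifted lists and 0 others were called.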

Results

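RNA of RAW 264.7 cells, a mouse macrophage-like line, was measured on 6 expression arrays. The cells had been transfected with 50 nM of a locked nucleic acid GapmeR, an antisense oligonucleotide that directs RNase H to its target RNA, and RNA was collected 48 h later. In 3 samples the GapmeR was a non-targeting control (Control), and in 3 it targeted Mist (Mist-targeted), a long noncoding RNA of macrophages transcribed near the fatty acid binding protein gene Fabp5. The comparison asks which transcripts differ when Mist is targeted. The annotation used here named 0 probe sets Mist, so the level of the target itself was not analysed here, and the groups rest on the labels, which name 1 GapmeR against Mist. Values were log2 expression for 41345 probe sets, which gave 22180 genes a probe set of their own. The arrays had medians between 4.47 and 4.50, and their number limits the precision: the median SE of a difference was 0.11 on the log2 scale.

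Among genes at an adjusted p under 0.05, the largest rise was that of the E3 ubiquitin ligase gene Neurl3. It rose 3.54-fold (log2 difference 1.83 ± 0.14, SE, n = 3 per group, limma, adjusted p = 0.0069, probe set 17222149). The PYHIN family genes Ifi209 and Ifi205 rose by 1.72 ± 0.12 and 1.62 ± 0.15, with the limit that probes of such related genes can share sequence, and the monocyte chemoattractant Ccl2 rose 3.03-fold, from 8.63 ± 0.085 to 10.23 ± 0.18 (mean ± SD of log2 values, n = 3 each). Ddit4, an inhibitor of mTORC1 signalling, was 3.52-fold lower with the Mist-targeted GapmeR (log2 difference -1.82 ± 0.16, SE; adjusted p = 0.014; probe set 17241032). The chemokine Ccl5 fell by 1.59 on the log2 scale, from 8.94 ± 0.044 to 7.35 ± 0.18 (mean ± SD, n = 3 each).

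At an adjusted p under 0.05, 92 genes changed, of which 47 rose and 45 fell, and 37 of the 92 changed at least 2-fold (20 rose and 17 fell). The largest other rises were Aif1, which encodes the macrophage actin-binding protein Iba1 (1.52 ± 0.091), Cfb, complement factor B (1.44 ± 0.10), the nucleic acid sensor gene Zbp1 (1.39 ± 0.094), the secreted macrophage protein gene Cd5l (1.19 ± 0.14), Trim30d (1.15 ± 0.15) and the myeloid receptor gene Cd300e (1.15 ± 0.11). The largest other falls were the mitochondrial folate enzyme gene Aldh1l2 (-1.50 ± 0.15), Ifi27 (-1.36 ± 0.096), the cystine transporter gene Slc7a11 (-1.33 ± 0.095), the transcriptional repressor Bhlhe41 (-1.23 ± 0.13), the heparanase gene Hpse (-1.18 ± 0.12), the kinase gene Plk2 (-1.16 ± 0.11), the pseudokinase gene Trib3 (-1.15 ± 0.14) and Cth, cystathionine gamma-lyase (-1.14 ± 0.11). Adjusted p values of these 14 genes lay between 0.0053 and 0.039. Ddit4, Cd5l, Trim30d, Mx1 and Il1b each had 1 group mean below the median of every array (4.22, 4.13, 4.05, 4.36 and 3.85); no measure of background was used here, so the sizes and ranks of these 5 differences are uncertain and may be understated. Over all 41345 probe sets, the groups did not overlap in 15.9%, where chance gives 10%.

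**Figure D1:**
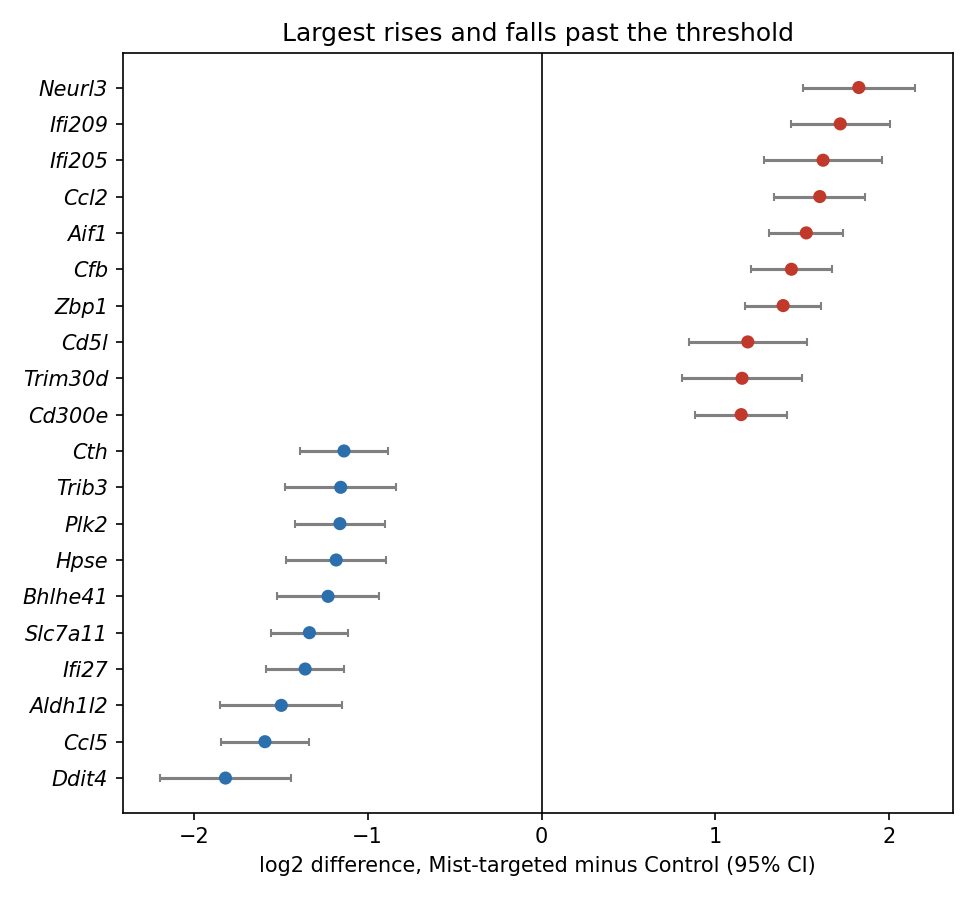
Log2 difference, Mist-targeted minus Control, of the 10 largest rises and the 10 largest falls among genes past the threshold (points; bars are 95% confidence intervals from the limma fit, n = 3 per group). The differences run from -1.82 for Ddit4 to 1.83 for Neurl3.

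Interferon-stimulated genes were higher as a group with the Mist-targeted GapmeR. All 34 measured members of this list had a positive difference, with a median of 0.40 on the log2 scale, and the list rose against the other genes (camera, adjusted p = 1.4e-31; adjusted p = 0.087 with an estimated correlation). Of the 34, 4 rose over all probe sets tested and 30 rose adjusted over the list alone. The 4 were Zbp1, the antiviral GTPase gene Mx1 (0.79 ± 0.088), the interferon signalling gene Stat2 (0.67 ± 0.079) and Ifi35 (0.65 ± 0.081). Cxcl10, an interferon-induced chemokine, had a difference of 0.31 ± 0.097 (adjusted p = 0.32). Ifi27, which is not on the list, fell although it too is named for its induction by interferon.

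Of the 27 inflammatory cytokines and chemokines, Ccl2, Il1b and Il18 rose, Ccl5 fell and 23 did not pass. Il1b, the interleukin 1 beta gene, rose from a low level of 3.85 ± 0.12 to 4.75 ± 0.17 (mean ± SD, n = 3 each; adjusted p = 0.039), and Il18 rose by 0.87 ± 0.11. Tnf differed by 0.14 ± 0.097 (adjusted p = 0.72), Il6 by 0.11 ± 0.089 (adjusted p = 0.77) and the inducible nitric oxide synthase gene Nos2 by -0.71 ± 0.14 (adjusted p = 0.12). Members lay on both sides of 0, 14 above and 13 below, with a median of 0.0037, and adjusted over the list alone 4 rose and 5 fell. The list was not called (camera, adjusted p = 0.88).

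**Figure D2:**
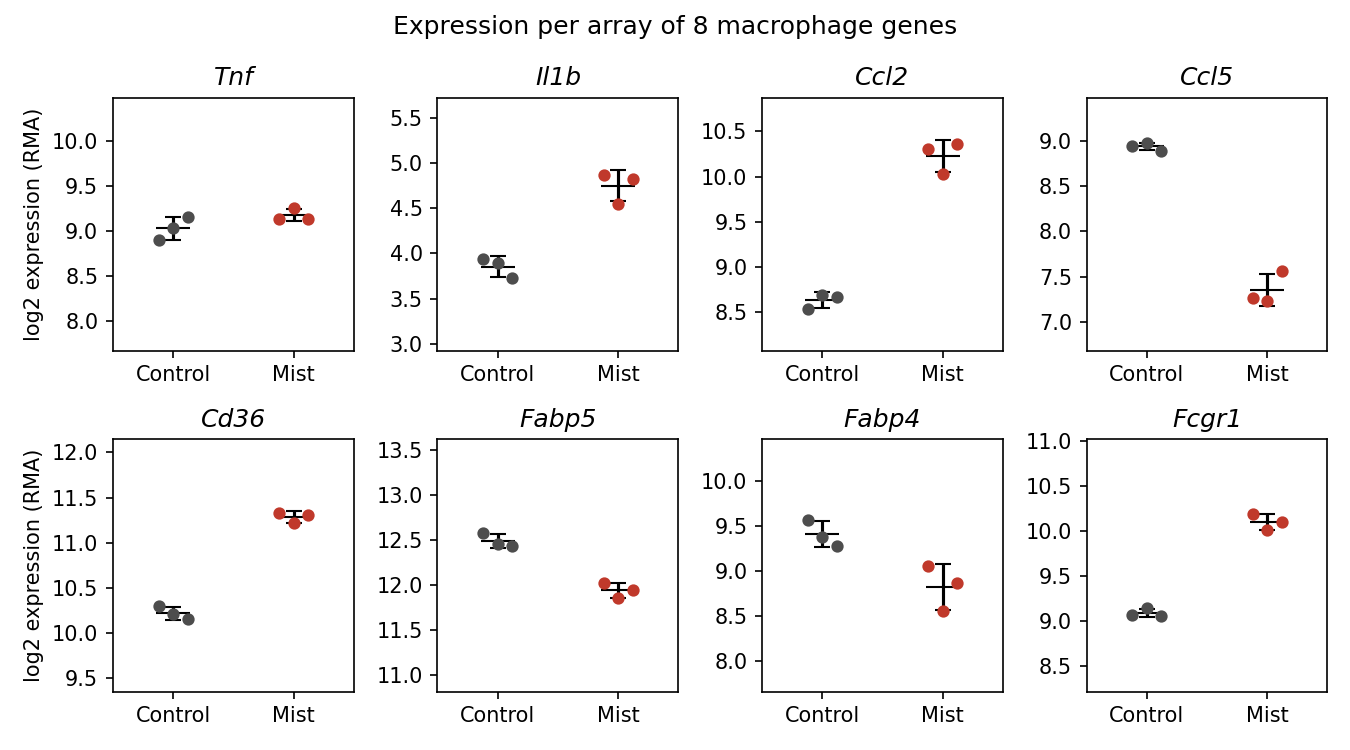
Log2 expression (RMA) on each array of Tnf, Il1b, Ccl2, Ccl5, Cd36, Fabp5, Fabp4 and Fcgr1, by GapmeR; points are arrays, and lines and bars are the mean and SD (n = 3 per group). In the panels of Il1b, Ccl2, Cd36 and Fcgr1 the Mist-targeted arrays lie above the Control arrays, in those of Ccl5, Fabp5 and Fabp4 below, and in that of Tnf the groups overlap.

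Among lists of macrophage sensing and identity, few members passed the test. None of the 20 genes of the NF-kB pathway and its feedback passed over all probe sets tested, and adjusted over the list alone 4 rose and 3 fell (camera, adjusted p = 0.94). Ier3 had a difference of -0.98 ± 0.22 and Irf1 one of 0.40 ± 0.090. None of the 23 genes of toll-like receptor and nucleic acid sensing passed, and adjusted over the list alone 6 rose and 1 fell (camera, adjusted p = 0.12). The DNA-sensing receptor gene Tlr9 differed by 0.55 ± 0.084 (adjusted p = 0.061) and the kinase gene Irak2 by -0.64 ± 0.089 (adjusted p = 0.0502). Of 20 alternative activation markers 0 passed, and 1 fell adjusted over the list alone (camera, adjusted p = 0.50). Arginase 1, Arg1, differed by -0.10 ± 0.092, the mannose receptor gene Mrc1 by 0.20 ± 0.12, and Egr2 by -0.68 ± 0.10 (adjusted p = 0.061). Of 19 macrophage identity genes, the high-affinity IgG receptor gene Fcgr1 rose 2.01-fold (1.01 ± 0.086), adjusted over the list alone 1 rose and 1 fell, and the list was not called (camera, adjusted p = 0.66). Csf1r, the receptor of the macrophage growth factor CSF1, differed by -0.11 ± 0.097. The antigen presentation list rose (15 members, 13 of them positive, median 0.13; camera, adjusted p = 3.0e-05; adjusted p = 0.087 with an estimated correlation). None of its members passed over all probe sets tested and 5 rose adjusted over the list alone. Among these 5 were the costimulatory ligand gene Cd80 at 0.68 ± 0.11 and the immunoproteasome gene Psmb10 at 0.44 ± 0.083. The presenting molecule genes H2-K1, H2-Aa, H2-Ab1, H2-Eb1 and B2m were chosen for naming after their values were seen. They differed by 0.04, -0.01, 0.06, 0.04 and 0.07.

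Hypoxia targets were lower on all 3 Mist-targeted arrays. All 15 measured members had a negative difference, the median was -0.81 on the log2 scale, and the list fell (camera, adjusted p = 5.9e-22; adjusted p = 0.14 with an estimated correlation). Ddit4 and the endoplasmic oxidoreductase gene Ero1a (-1.08 ± 0.13) fell over all probe sets tested, and 13 members fell adjusted over the list alone. Vegfa (-1.57 ± 0.34) and Ndrg1 (-1.58 ± 0.27) were chosen for naming after their values were seen and had adjusted p values of 0.15 and 0.080. The medians of the Mist-targeted arrays against the Control mean were -1.17, -0.67 and -0.75. All 15 glycolysis genes also had negative differences (median -0.32; camera, adjusted p = 8.3e-10; adjusted p = 0.30 with an estimated correlation). None of them passed over all probe sets tested and 6 fell adjusted over the list alone, with the glucose transporter gene Slc2a1 at -0.91 ± 0.19 (adjusted p = 0.13) and the phosphofructokinase gene Pfkp at -0.66 ± 0.13 (adjusted p = 0.13). The Mist-targeted arrays had glycolysis medians of -0.64, -0.27 and -0.16, and without Mist-targeted replicate 1 the median difference of the list was -0.20.

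Genes of the integrated stress response, most of them targets of the transcription factor ATF4, were lower as well. Of 19 members 18 had a negative difference, with a median of -0.47, and the list fell (camera, adjusted p = 2.5e-20; adjusted p = 0.087 with an estimated correlation). Trib3, Cth, Ddit3 (-0.93 ± 0.11), Ppp1r15a (-0.81 ± 0.10) and Chac1 (-0.80 ± 0.11) fell over all probe sets tested, and 14 fell adjusted over the list alone; Chac1 was chosen for naming after its value was seen. Of the 17 endoplasmic reticulum chaperone genes 0 passed and 3 fell adjusted over the list alone (camera, adjusted p = 0.26), with Herpud1 at -0.36 ± 0.093 and Xbp1 at -0.35 ± 0.092. Of 18 NRF2 targets and redox genes Slc7a11 fell, and adjusted over the list alone 1 rose and 2 fell (camera, adjusted p = 0.19). Of 20 p53 targets Plk2 fell, and adjusted over the list alone 3 rose and 4 fell (camera, adjusted p = 0.50). The heat shock list rose (15 of 16 members positive, median 0.16; camera, adjusted p = 0.0033; adjusted p = 0.13 with an estimated correlation), although its member with the smallest p, Hspa4l, differed by -0.36 ± 0.078 (adjusted p = 0.14) and was the 1 that fell adjusted over the list alone. The mean of the list was 0.13, of the same sign as its median.

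**Figure D3:**
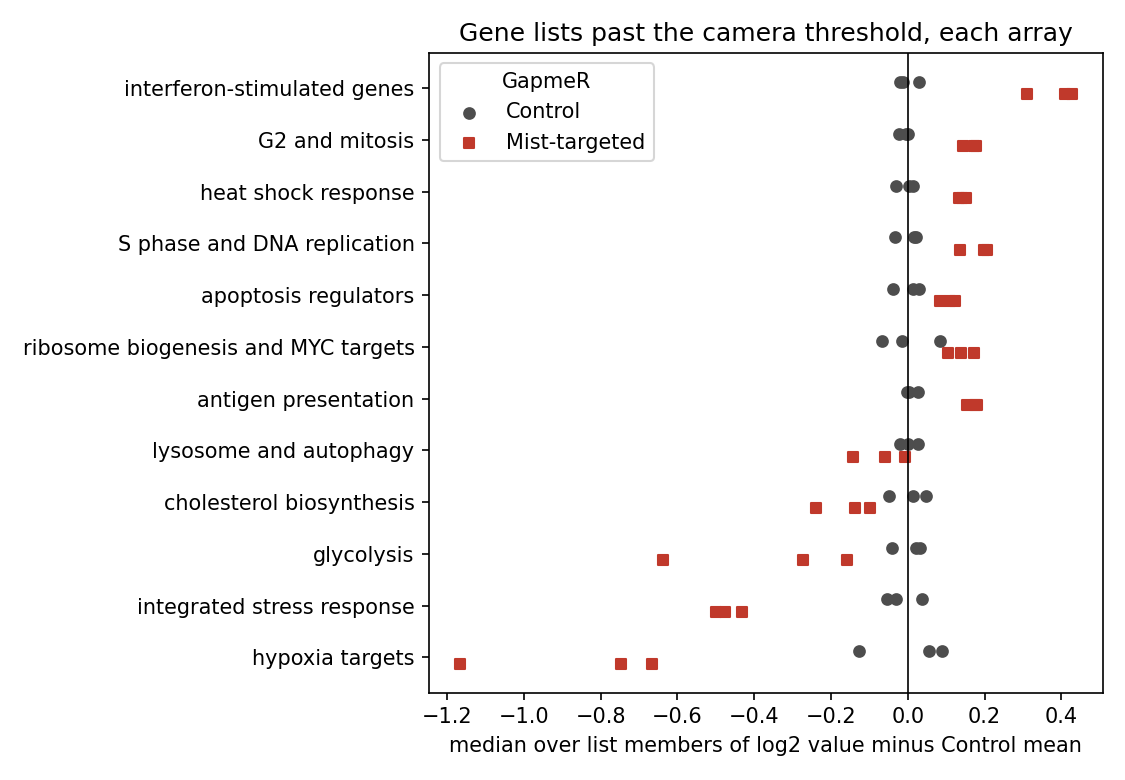
Median over list members of the log2 value minus the Control mean, on each array, for the 12 gene lists past the camera threshold (circles, Control; squares, Mist-targeted; n = 3 arrays each). Interferon-stimulated genes lie at 0.43, 0.31 and 0.41 and hypoxia targets at -1.17, -0.67 and -0.75 on the Mist-targeted arrays.

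In lipid handling, the scavenger receptor gene Cd36 rose and the lipid droplet gene Hilpda fell. Cd36 went from 10.22 ± 0.073 to 11.29 ± 0.062 (mean ± SD, n = 3 each; 2.10-fold; adjusted p = 0.0093), and Hilpda differed by -1.05 ± 0.14 (adjusted p = 0.047). The other 15 of the 17 measured genes of fatty acid binding and lipid storage did not pass, adjusted over the list alone 1 rose and 3 fell, and the list was not called (camera, adjusted p = 0.50). Fabp5 had a difference of -0.54 ± 0.089 (adjusted p = 0.076), or 1.46-fold lower, and its 4 probe sets had differences of -0.54, -0.55, -0.72 and -0.83, of which that at -0.72 fell (adjusted p = 0.027); Fabp5 has processed pseudogenes in mouse, and which of the 4 measure related copies was not checked here. Fabp4 had a difference of -0.58 ± 0.14 (adjusted p = 0.19). Among 12 genes around the Fabp cluster 0 passed over all probe sets tested and 2, Fabp5 and Fabp4, fell adjusted over the list alone (median -0.077; camera, adjusted p = 0.074). The value of this list rested on single arrays: without Mist-targeted replicate 1 the median was -0.16 (adjusted p = 0.012), without Mist-targeted replicate 2 it was -0.013 (adjusted p = 0.45), and without each of the other arrays the adjusted p lay between 0.058 and 0.17. Tested among listed probe sets only, an alternative chosen after seeing the data, Fabp5 and Fabp4 fell with adjusted p values of 0.0069 and 0.032.

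Of the 19 cholesterol biosynthesis genes 17 had negative differences (median -0.16), and the list fell (camera, adjusted p = 9.8e-05; adjusted p = 0.35 with an estimated correlation), with a median of -0.079 without Mist-targeted replicate 1. None passed alone, over all probe sets or over the list, with Lss at -0.33 ± 0.087 and Cyp51 at -0.30 ± 0.081. Of 15 LXR targets and lipogenesis genes 0 passed, and adjusted over the list alone 1 rose and 1 fell (camera, adjusted p = 0.97), with the cholesterol exporter gene Abca1 at 0.44 ± 0.096 and Scd1 at -0.31 ± 0.079. None of 18 fatty acid oxidation genes (camera, adjusted p = 0.73; Echs1 -0.27 ± 0.091) and none of 28 oxidative phosphorylation genes (camera, adjusted p = 0.85; Ndufv2 0.21 ± 0.085) passed either test. The lysosome and autophagy list fell by a small amount (19 of 25 members negative, median -0.066; camera, adjusted p = 0.041; adjusted p = 0.66 with an estimated correlation), with 0 members past either test and Hexa at -0.30 ± 0.090. That call ended without Control replicate 2 (adjusted p = 0.091), Control replicate 3 (0.064), Mist-targeted replicate 1 (0.36, with a median of -0.039) or Mist-targeted replicate 2 (0.097).

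Cell cycle genes were slightly higher with the Mist-targeted GapmeR. The S phase and DNA replication list rose (21 of 23 members positive, median 0.16; camera, adjusted p = 3.2e-08; adjusted p = 0.11 with an estimated correlation), and so did the G2 and mitosis list (21 of 23 positive, median 0.18; camera, adjusted p = 6.4e-06; adjusted p = 0.087 with an estimated correlation). None of their members passed over all probe sets tested, and adjusted over the list alone 7 S phase genes and 2 mitotic genes rose. The replication licensing gene Cdc6 differed by 0.50 ± 0.089, Fen1 by 0.42 ± 0.081, Aurka by 0.44 ± 0.094 and Plk1 by 0.34 ± 0.079. The list of ribosome biogenesis and MYC targets rose (17 of 19 positive, median 0.13; camera, adjusted p = 0.0033; adjusted p = 0.30 with an estimated correlation) with 0 members past either test; Myc itself differed by -0.48 ± 0.21 (adjusted p = 0.52; -0.73 without Control replicate 3 and -0.32 without Control replicate 2) and Wdr43 by 0.19 ± 0.079. Of 20 apoptosis regulators Bcl2l11, which encodes the pro-apoptotic protein BIM, rose (0.74 ± 0.088), and 3 rose adjusted over the list alone. That list rose (median 0.14; camera, adjusted p = 0.012; adjusted p = 0.15 with an estimated correlation), but not without Control replicate 3 (median 0.074; adjusted p = 0.053).

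Of 15 genes of the PARP family and PARG 0 passed, and adjusted over the list alone 2 rose and 1 fell (camera, adjusted p = 0.66). Parp1 differed by 0.060 ± 0.086 (adjusted p = 0.90), Parp14 by 0.48 ± 0.095 and Parp12 by 0.34 ± 0.079. Of 12 osteoclast genes Ocstamp, which acts in osteoclast fusion, rose 2.07-fold (1.05 ± 0.098), adjusted over the list alone 2 rose and 2 fell, and the list was not called (camera, adjusted p = 0.81). Markers of other cell types gave no called list. Among 11 T and NK cell genes Il7r, at a high level in this line, fell by 0.92 on the log2 scale from 10.40 ± 0.13 (mean ± SD, n = 3; camera for the list, adjusted p = 0.50), and among 7 dendritic cell genes Itgax fell by 0.84 (camera, adjusted p = 0.66). Both also fell adjusted over their list alone. None of 8 B cell (camera, adjusted p = 0.998), 11 neutrophil (0.97), 10 fibroblast (0.97) and 5 erythroid and mast cell genes (0.67) passed either test; examples are Pax5 at 0.13 ± 0.095, Camp at -0.26 ± 0.11, Dcn at 0.13 ± 0.081 and Cpa3 at -0.10 ± 0.096.

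Single genes were tested with limma and lists with camera. No list of the 33 was called with an estimated correlation (camera, lowest adjusted p = 0.087, with 8 lists at an unadjusted p under 0.05). Fry called 10 lists in 1 direction and 26 in either. The 26 include lists that camera did not call. An example is cytokines and chemokines (fry in either direction, adjusted p = 2.0e-05), whose members moved both ways. The number of genes called rests on every array: without Control replicates 1, 2 and 3 in turn it was 9, 1 and 13, and without Mist-targeted replicates 1, 2 and 3 it was 14, 34 and 3. Aif1 was the only gene called in all 6 of these fits, and 58 of the 92 were called in none. Median, mean and test of a list differed in sign for 6 lists that were not called: cytokines and chemokines, NF-kB, LXR targets, osteoclast genes, B cells and fibroblasts. An ordinary linear model without moderation called 0 genes (1414 were higher and 1514 lower at an unadjusted p under 0.05). By chance alone a share of about 0.05 of the 22180 genes would pass unadjusted. Limma on listed probe sets only, an alternative chosen after seeing the data, called 643 genes. Of these 243 rose and 400 fell, and they included all 92.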

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

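The number of calls depended on the model, the probe sets tested and the arrays; testing only listed probe sets was chosen after seeing the data. The main counts were 53 rises and 52 falls of probe sets and 47 and 45 of genes. With the replicate number as a replicate block, 0 probe sets and 0 genes rose or fell (limma, lowest adjusted p 0.072). At an unadjusted p under 0.05 in that fit, 1143 genes were higher and 1242 lower, where chance alone gives a share of about 0.05 of 22180. Residuals of arrays with the same number correlated at 0.20, 0.096 and 0.033. Those of arrays with different numbers correlated at -0.15 to 0.060, the highest for Control replicate 3 with Mist-targeted replicate 2. The main fit was planned without a block, and the labels do not say what the numbers stand for. A shared effect of the replicate number, such as a batch, was not excluded. An ordinary model gave 0 probe sets and 0 genes in each direction (lowest adjusted p 0.061), with few residual degrees of freedom. Trend and robust gave 117 and 170 probe sets and 95 and 146 genes. Without the dimmest 40% of probe sets, 88 probe sets and 78 genes fell. The mean of all probe sets per gene gave 270 and 428 genes. That fit also left out unlisted probe sets, and only 1082 of its 22180 genes had more than 1 probe set to average. Listed probe sets only gave 275 and 446 probe sets and 243 and 400 genes; unlisted probe sets varied more within groups (median SD 0.186 against 0.118). Leaving out each array in turn, probe sets rose 2 to 27 and fell 0 to 13, and genes rose 1 to 22 and fell 0 to 12, with fewer samples in each fit. Of 12 lists, 7 up and 5 down, 0 in either direction were called with an estimated correlation. Fry in 1 direction called 2 down, losing cholesterol biosynthesis, glycolysis and lysosome (fry, adjusted p 0.099, 0.106 and 0.27). It called 8 up, adding toll-like receptor and nucleic acid sensing (fry, adjusted p 0.017). The lysosome list also lost its call without the dimmest probe sets, with quantile normalization, array weights and the mean of probe sets. Blk had a difference of 0.088 ± 0.12 (limma, adjusted p = 0.89). It ranged from -0.022, without Mist-targeted replicate 2, to 0.17, without Mist-targeted replicate 3. The sign change rested on Mist-targeted replicate 2, at 4.84 beside 4.55 and 4.46 in Mist-targeted replicates 1 and 3. Why that array was higher was not tested. Quantile normalization, median centring and array weights kept the counts within 1.5 times. Quantile normalization and median centring are weak tests here, because the array medians were already alike. The 1.5-fold minimum could not change the gene counts, because every called gene already differed by more than that. It also left the probe sets at 53 rises and 52 falls. Of 35 named genes past the threshold, 34 kept their call with median centring and 1 to 17 with an array left out, and of 50 not past it 18 passed among listed probe sets. Probe sets near the low end of signal bound small changes.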

Other observations

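The genes of this and the next paragraph, the screen of gene families, and the tests of 1 array, of the oligonucleotide, of oxygen or cell density and of the shared change of 2 lists were chosen only after the results were seen. Genes were grouped into 591 families by the stem of their symbol and tested with camera. The Ifi family of interferon-inducible genes (14 members, 13 positive, median 0.52), the Ifit family (6 members, all positive, median 0.40) and the Gbp family of guanylate-binding proteins (10 members, 9 positive, median 0.34) rose, and Tbc (31 members, 24 negative, median -0.12), Exoc, subunits of the exocyst (12 members, 10 negative, median -0.18), and Vps genes of vesicle sorting (33 members, 21 negative and 12 positive, median -0.061) fell. Their directions held with quantile normalization and with median centring, which are weak tests here because the array medians were already alike. At the preset correlation their adjusted p values ran from 4.5e-10 for Ifi to 0.048 for Vps (camera). None of the 6 was called with an estimated correlation (camera, adjusted p = 0.99). Genes such as Ifit1, Ifi35 and Gbp3 also stand on the interferon-stimulated list, so the rises of the Ifi, Ifit and Gbp families are no separate evidence. The Ifitm family was not called (6 members, 5 negative, camera, adjusted p = 0.91). The interferon genes looked at did not pass: Ifnb1 had a mean of 3.69 and a difference of -0.021 ± 0.14, Ifng a mean of 4.07 and a difference of -0.18 ± 0.12, and Ifna4 a difference of -0.24 ± 0.17 (limma, adjusted p = 0.99, 0.73 and 0.72). Irf9, whose product acts with that of Stat2 in interferon signalling, had a mean of 8.28 and a difference of -0.0020 ± 0.12 (limma, adjusted p = 0.997).

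The hypoxia-induced peptide gene Adm had a difference of -3.00 ± 0.73 (SE, n = 3 per group; limma, adjusted p = 0.19), with Mist-targeted arrays at 4.34, 7.48 and 7.05 against 9.40 and 9.48 in Control replicates 1 and 2 and 9.0 in Control replicate 3. Cd274, which encodes the immune checkpoint ligand PD-L1, fell by 0.98 on the log2 scale (adjusted p = 0.038), and Acod1, which encodes the enzyme that makes itaconate, fell by 0.87 (adjusted p = 0.031), in the same arrays in which interferon-stimulated genes rose. Uty, a gene of the Y chromosome, fell by 0.73 (adjusted p = 0.033), while the Y-linked genes Kdm5d and Eif2s3y differed by -0.10 and -0.021 and did not pass (adjusted p = 0.80 and 0.98).

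Interferon-stimulated genes were higher with the Mist-targeted GapmeR. The members were split by name into 20 taken as outside multigene families and 14 in families. The 20 had a median of 0.37 (bootstrap 95% interval over members 0.31 to 0.43), beside 0.54 for the 14. The rise was thus not confined to the 14. Several of the 20, such as Irf7, Stat2 and Parp14, have relatives of the same symbol stem, and no probe sequences were compared. The split therefore cannot exclude cross-hybridization between related genes. A shift of genes of that expression level was argued against, since the list lay at percentile 100 of 10000 random lists matched on mean expression (central 95% -0.057 to 0.081). The median of the whole list stayed at 0.38 or above without any 1 array. An effect of the oligonucleotide itself, which might be sensed as foreign nucleic acid, cannot be told apart from loss of Mist, because only 1 GapmeR against Mist was used.

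Hypoxia targets were lower with the Mist-targeted GapmeR. Their median lay at percentile 0 of matched random lists (central 95% -0.098 to 0.11), which argues against a shift of genes of that expression level, and without the array whose removal weakened it most, Mist-targeted replicate 1, it was -0.66. A different oxygen level or cell density in the 2 sets of cultures may give such a fall and cannot be told apart from the GapmeR, because 0 arrays have a value for either in the labels. An effect of targeting Mist stays open as a hypothesis.

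Genes of the integrated stress response were lower too, at percentile 0 of matched random lists (central 95% -0.082 to 0.099), which argues against a shift of genes of that expression level. The median was -0.42 or lower without any 1 array. Whether this is the same change as that of the hypoxia targets cannot be told apart: over the 3 Mist-targeted arrays the medians of both lists had a correlation of 0.66, and 3 arrays are too few to test it. An effect of the GapmeR on both remains a possible explanation.

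The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 105 probe sets, 92 genes and 12 lists, and only this 1 of the 10 splits reached each of these counts. The other splits gave 0 probe sets and 0 genes each and 0 to 7 lists, so camera also called lists in mixed groups. Each other split puts arrays of both GapmeRs in each group, so a real difference widens the spread and lowers the gene count. The 0 genes there are no measure of false calls. Mixed groups also keep part of a real difference, so the lists called there are no measure of false calls either.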
